A study of Mus musculus with 10 samples.

How the data were processed

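RNA-seq libraries of 10 mouse glioma cell samples were analysed, all of mixed strain and grown in serum-free DMEM/F12 with FGF, EGF, ITS, heparin and progesterone, per the labels' protocols. Total RNA was extracted with RNeasy kits, per the labels' protocols. The genotype labels gave 3 groups. PPO1 (n = 4) carried floxed Pten and Trp53 with Cre under Olig1, PPO2 (n = 4) carried the same floxed genes with Cre under Olig2, and OPN (n = 2) carried floxed Nf1 and Trp53 with Cre under Olig1. A floxed gene is one flanked by sites at which the Cre recombinase cuts out the DNA between them. Replicate numbers were taken from the sample titles, so that the OPN libraries are replicates 2 and 3. The labels do not say whether the libraries of a group came from separate cultures or animals, and the p-values then measure only the spread between these samples, part of which may be technical. Sex-linked genes went opposite ways within each group, as in OPN replicates 2 and 3 with Xist at 0.28 and 905 CPM and Ddx3y at 45.5 and 0.06 CPM, so the libraries of a group are not all repeats of 1 sample.

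The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.8.1, STAR 2.6.1e, featureCounts 1.6.2, DESeq2 and DESeq, and the genome builds GRCm38 and mm10. The role and settings of each tool, the strandedness of the libraries and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes, of near-identical paralogs such as the histone and H2 genes and of the Scd family therefore may be shared between gene entries. The deposited count table holds raw read counts for 35869 gene symbols, and a second deposited table holds TPM, which the authors scaled to the same total in each library and rounded. Each of these tables has 4 columns that match no sample of this series, and these 8 columns were not used. In the symbol column 27 entries had been converted to dates and held at most 0.351% of the counts of a library; they were kept as written. Symbols matched the RefSeq gene table of GRCm38.p6 for 32401 entries, and coordinates are from that table.

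The libraries held 28308661 to 40443907 counted reads. Library pairs within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 97.6 to 405.5, and every library was kept as 1 replicate. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 19380 genes, libraries were scaled with TMM, and all 10 libraries entered 1 quasi-likelihood fit with robust estimation and a term per group. Each pair of groups was compared with the quasi-likelihood F-test, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts per TMM-scaled library total, given as mean ± SD over n libraries, and log2 fold changes are given ± their standard error.

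Before the data were examined, the groups, the tests, the processing alternatives, the rule for named genes and 33 gene lists were fixed. The lists covered the engineered loci, oligodendrocyte progenitors, myelinating oligodendrocytes, neural stem cells and radial glia, transit-amplifying progenitors, neuroblasts and neurons, astrocytes, mesenchymal glioma, proliferation, cell-cycle regulators, p53 targets, RAS-MAPK output, FOXO targets, cholesterol synthesis, receptor tyrosine kinases, and the Notch, Hedgehog, Wnt, and TGF-beta and BMP pathways. They also covered forebrain identity, the Hox clusters, interferon response, MHC class I presentation, hypoxia and glycolysis, extracellular matrix, immediate-early genes, heat shock and unfolded protein response, microglia and macrophages, endothelial cells, pericytes and fibroblasts, sex-linked genes, mitochondrially encoded genes and replication-dependent histones. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, and p-values were adjusted over the lists of a comparison. Counts of called members were also adjusted over the list alone. Some genes belong to more than 1 list.

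The rule for named genes took the engineered loci and, in each comparison, the 10 largest rises and 10 largest falls. These came from the called genes with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, without predicted or clone genes. From each list described it took up to 4 called members with the largest change, or, where none was called, up to 2 members with the highest mean CPM, and it took the sex-linked genes in every library. Genes outside this rule are said to have been chosen after their values were seen. Library similarity was described with principal components and Spearman correlations of log2 CPM over the tested genes. The overlap of both OPN comparisons was set beside 20 simulations of unchanged groups that shared the OPN libraries and beside the overlap of independent lists.

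The tests were tested on simulated counts in which 200 genes with a mean of at least 5 CPM were changed by 2-fold, 4-fold or 8-fold. Recovery of changed genes at lower levels was not tested. For PPO2 vs PPO1, edgeR recovered 4.5%, 53.7% and 81.8% of the genes changed by these folds, with 2 false calls among 95. For OPN vs PPO1 it recovered 3%, 35.8% and 65.2%, with 2 false calls among 71, and for OPN vs PPO2 3%, 35.8% and 66.7%, with 3 false calls among 73. DESeq2 made 65 false calls among 198, 97 among 216 and 94 among 211 in the same order. A list of 20 genes raised by 2-fold was recovered by each of the list tests in every comparison, and 0 or 1 of 30 unshifted lists were called. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.894, for the mitochondrially encoded genes. The simulation therefore does not check false calls of lists whose genes vary together.

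The alternatives were RLE scaling, library totals alone, no filter, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, and glmTreat above an absolute log2 fold change of 1. Others were limma on log2(TPM + 1) with a filter of 1 TPM in at least 2 libraries, on log2(TPM + 0.1), and without a filter, and the omission of each library. Thinning of every library to the lowest total and a GC correction per library with a loess span of 0.5 were added after the data were seen. GC content was taken from GENCODE M21 transcripts and was found for 88.5% of the tested genes. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.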

Results

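Gene expression was measured by RNA-seq in 10 mouse glioma cell samples from 3 genotypes. PPO1 (n = 4) and PPO2 (n = 4) carried floxed Pten and Trp53, with Cre under Olig1 and Olig2, and OPN (n = 2) carried floxed Nf1 and Trp53 with Cre under Olig1. The tumour suppressor Pten opposes PI3K signalling, Nf1 encodes a RAS GTPase-activating protein, and Trp53 encodes p53. Library totals were 32934530 to 34500508 counts in PPO1, 28308661 to 32857303 in PPO2 and 39129336 to 40443907 in OPN.

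The engineered loci were read first. Pten (GRCm38.p6 chromosome 19, 32757577 to 32826160) was at 126 ± 11.8 CPM (SD, n = 4) in PPO1, 117 ± 20.2 CPM (SD, n = 4) in PPO2 and 120.2 ± 15.4 CPM (SD, n = 2) in OPN. Nf1 (chromosome 11, 79339590 to 79581609) was at 219.6 ± 30.0 CPM in PPO1, 173.9 ± 73.1 CPM in PPO2 and 112 ± 21.01 CPM in OPN. Its single libraries lay at 97.1 and 127 CPM in OPN and at 112.5 to 280.0 CPM in the PPO libraries. Trp53 (chromosome 11, 69580348 to 69591873) was at 13.5 ± 0.556 CPM in PPO1, 16.6 ± 6.34 CPM in PPO2 and 26.8 ± 6.51 CPM in OPN. Olig1 (chromosome 16, 91269769 to 91271939) was at 292 ± 238 CPM in PPO1, 391 ± 239 CPM in PPO2 and 1271 ± 188 CPM in OPN. Olig2 (chromosome 16, 91225550 to 91228677) was at 243 ± 165 CPM, 306 ± 168 CPM and 672 ± 122 CPM in the same order. None of these genes was called by edgeR in any comparison, and the smallest adjusted p was 0.136, for Trp53 and Olig1 in OPN vs PPO1. Adjusted over these 5 genes alone, Trp53 and Olig1 were higher and Nf1 was lower in OPN than in PPO1 (adjusted p = 0.0329 for each). A floxed deletion of some exons need not lower the count of a whole gene, so these levels do not check the genotype labels.

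The OPN libraries lay apart from the PPO libraries on the first principal component and correlated most with each other. PPO1 and PPO2 libraries were interspersed. The first principal component held 28.3% of the variance and placed OPN replicates 2 and 3 at 90.8 and 125.2. On the same axis the PPO libraries lay between -87.2 and 63.0. The second component held 21.7% of the variance and placed OPN replicates 2 and 3 at -97.5 and -39.4. Between them lay PPO2 replicate 3 (-65.1), PPO1 replicate 4 (-51.0) and PPO2 replicate 4 (-45.3). The sex-linked genes Ddx3y, Eif2s3y and Xist had the largest weights on this component. Spearman correlations across genes were 0.971 within OPN, 0.908 to 0.969 within PPO1 and 0.917 to 0.951 within PPO2. They were 0.895 to 0.979 between PPO1 and PPO2, 0.878 to 0.946 between PPO1 and OPN and 0.879 to 0.923 between PPO2 and OPN. PPO1 replicate 3 stood apart on the third component, which held 13.9% of the variance, at -127.2. Xist, the RNA of the inactive X chromosome, was at 364 to 489 CPM in PPO1 replicates 1 and 2 and PPO2 replicates 1 and 2, and at 905 CPM in OPN replicate 3. The Y-linked gene Ddx3y was at 42.7 to 131 CPM in PPO1 replicate 4, PPO2 replicates 3 and 4 and OPN replicate 2. PPO1 replicate 3 had 2.1 CPM of Xist and 0.61 CPM of Ddx3y.

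**Figure D1:**
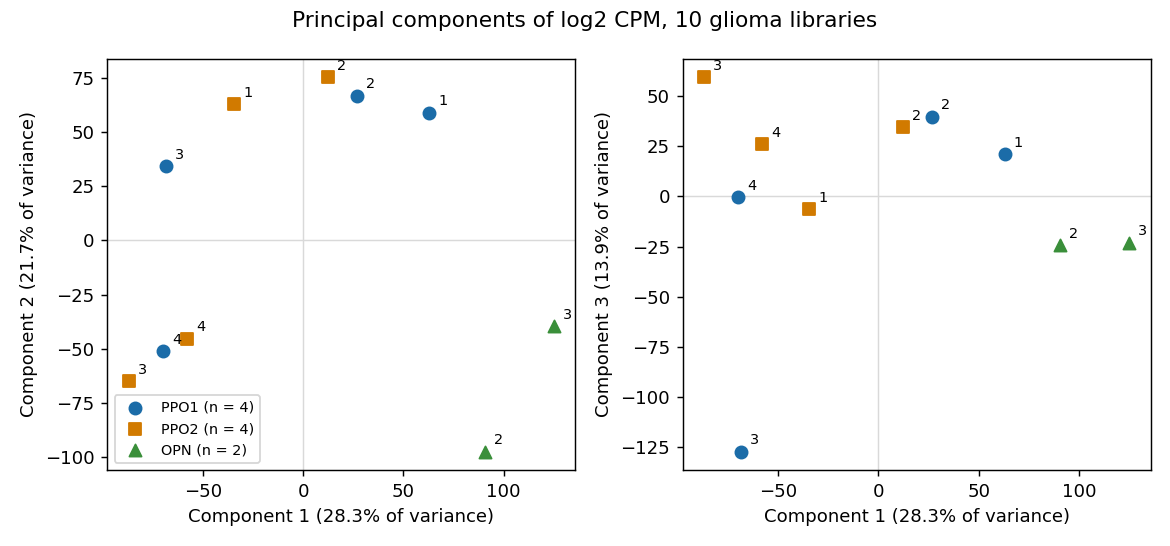
Principal components of log2 CPM over the tested genes, with component scores on both axes and 1 point per library, coloured by group. The OPN libraries sit at 90.8 and 125.2 on the first component, and PPO1 replicate 3 sits at -127.2 on the third.

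PPO2 was compared with PPO1, which carry the same floxed genes and differ in the Cre driver. The oligodendrocyte progenitor genes were lower in PPO2 as a list, with a median log2 fold change of -1.41 and 17 of 20 members lower (camera adjusted p = 0.000275; adjusted p = 0.892 with an estimated correlation). Ptprz1, a receptor phosphatase of progenitor cells, was at 985 ± 713 CPM (SD, n = 4) in PPO1 and 476 ± 274 CPM (SD, n = 4) in PPO2, and Ncan, a brain proteoglycan, was at 477 ± 314 and 487 ± 377 CPM. The Hedgehog pathway genes were higher in PPO2 as a list, with a median of 0.98 and all 12 members higher (camera adjusted p = 0.00248; adjusted p = 0.412 with an estimated correlation). The receptors Ptch1 and Gas1 had log2 fold changes of 0.29 ± 0.52 and 0.80 ± 0.56. The gene with the smallest p, named after its value was seen, was Dusp15, which encodes a dual-specificity phosphatase and lies on chromosome 2 at 152940995 to 152952400. It was at 33.4 ± 14.6 CPM in PPO1 and 1.95 ± 0.925 CPM in PPO2, a log2 fold change of -4.09 ± 0.47 with an edgeR adjusted p of 0.139.

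No gene was called between PPO2 and PPO1 by edgeR's quasi-likelihood test, with 1050 genes at an unadjusted p under 0.05. DESeq2 called 66 genes, and limma on the TPM values called 0. By camera, the progenitor and Hedgehog lists passed the threshold, and neither did with an estimated correlation. By fry, 0 of the 33 lists passed, the lowest adjusted p being 0.487. The immediate-early list was also lower by camera (median -0.60, adjusted p = 0.00428), and so was the astrocyte list (median -0.43, adjusted p = 0.00797). The proliferation list was higher (median 0.40, camera adjusted p = 0.00797). For each of these camera gave adjusted p = 0.892 with an estimated correlation. Without a camera call, 12 of 14 microglia and macrophage markers were lower (median -2.28, camera adjusted p = 0.455), with Laptm5 at 25.3 CPM in PPO1 replicate 4 and at most 1.09 CPM in the other PPO1 libraries, and so were 12 of 14 MHC class I genes (median -0.45, camera adjusted p = 0.176). Adjusted over the list alone, 1 progenitor gene and 3 immediate-early genes were lower, and no gene of the Hedgehog, astrocyte or proliferation lists was called. In lists that camera did not call, the receptor tyrosine kinase genes Ntrk2 and Fgfr3 were lower and the Wnt gene Axin2 was higher when adjusted over the list alone (adjusted p = 0.0199, 0.0409 and 0.0191); Fgfr3 and Axin2 are named after their values were seen. Among the members, Egr1, an immediate-early transcription factor, had a log2 fold change of -1.60 ± 0.60 and Jun 0.18 ± 0.46. The astrocyte genes Apoe and Sparcl1 had values of -0.81 ± 0.66 and -0.42 ± 0.53, and the proliferation genes Top2a and Pcna 0.13 ± 0.65 and 0.12 ± 0.19. The neurotrophin receptor Ntrk2 was at 766 ± 354 CPM in PPO1 and 218 ± 79.8 CPM in PPO2, with an edgeR adjusted p of 0.887. The other 28 lists had camera adjusted p-values of 0.0615 to 0.890, and among them the Wnt, extracellular matrix, interferon response, and heat shock and unfolded protein response lists had a median below 0 and a test direction above 0. The camera call ended for the astrocyte list without PPO1 replicate 1 (adjusted p = 0.380) or PPO2 replicate 3 (0.334), and for the proliferation list without PPO1 replicate 2 (0.964) or PPO2 replicate 4 (0.506). It ended for the immediate-early list without PPO1 replicate 4 (camera adjusted p = 0.242) or PPO2 replicate 2 (0.0592).

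OPN was compared with PPO1, which shares its Cre driver and floxed Trp53 and differs in Nf1 against Pten. Genes that fell in OPN included Nupr1, Cdkn1a and Trib3, and genes that rose included A2m and Hr. Nupr1, a stress-induced chromatin protein (chromosome 7, 126623246 to 126625470), was at 278 ± 98.7 CPM (SD, n = 4) in PPO1 and 13.8 ± 3.54 CPM (SD, n = 2) in OPN, 20.1-fold lower. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090979 to 29100722), was at 80.9 ± 31.3 and 8.62 ± 1.47 CPM, 9.38-fold lower. In the other direction, A2m, which encodes a secreted protease inhibitor (chromosome 6, 121636165 to 121679238), was at 3.65 ± 3.31 CPM in PPO1 and 695 ± 14.5 CPM in OPN, 190.3-fold higher. The nuclear corepressor gene Hr (chromosome 14, 70554056 to 70573548) rose from 6.26 ± 3.42 to 206 ± 27.7 CPM.

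The 10 largest rises by the naming rule were A2m, Aldh1a1, Hr, Prdm16, Baalc, Adra2a, Sox3, Rasgrp1, Wnt5b and Scd3, with log2 fold changes from 7.57 ± 1.49 for A2m to 3.43 ± 0.36 for Scd3. Aldh1a1, a retinaldehyde dehydrogenase, rose by 5.69 ± 0.80, the transcriptional regulator Prdm16 by 4.60 ± 0.95, and the progenitor transcription factor Sox3 by 4.21 ± 0.67. Rasgrp1, a RAS guanine nucleotide exchange factor, rose by 4.16 ± 0.69. Scd3 encodes a stearoyl-CoA desaturase and may share reads with its paralogs. The 10 largest falls were Cpne7, Lgi2, Nupr1, Sphk1, Trib3, Cth, Fbln1, Tspan18, Ier3 and Bche, with log2 fold changes from -6.73 ± 1.16 for Cpne7 to -3.55 ± 0.74 for Bche. Sphk1, a sphingosine kinase, fell by 4.10, and Cth, an enzyme that makes cysteine, fell by 3.71. The edgeR adjusted p-values of these 20 genes lay between 0.0184 and 0.0493.

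**Figure D2:**
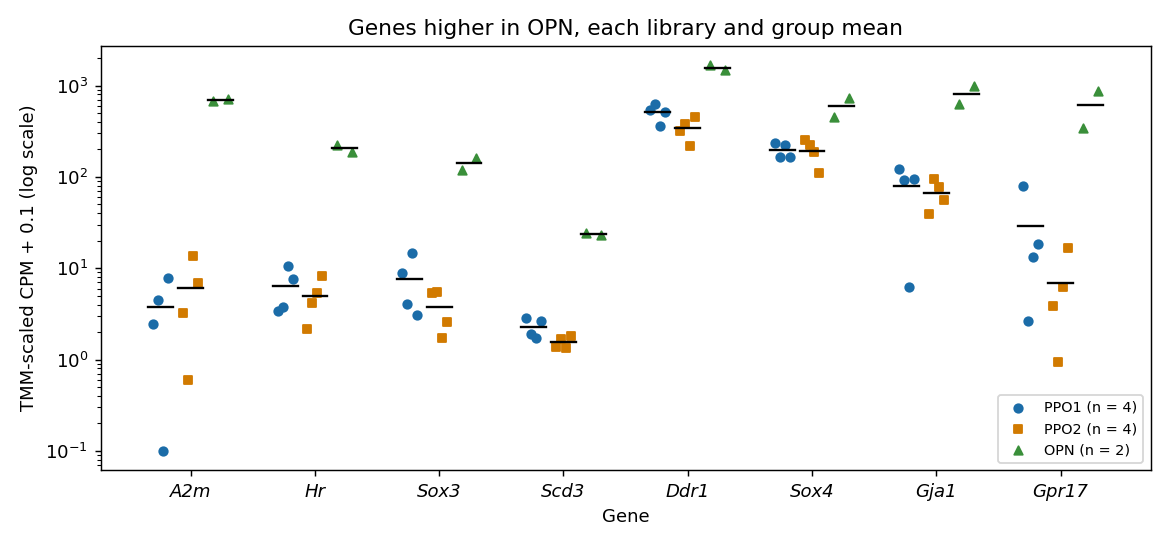
TMM-scaled CPM + 0.1 on a log axis for genes higher in OPN, with 1 point per library and a bar at each group mean. The OPN points of Hr lie at 187 and 226 CPM, above the PPO libraries at 2.09 to 10.5 CPM.

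**Figure D3:**
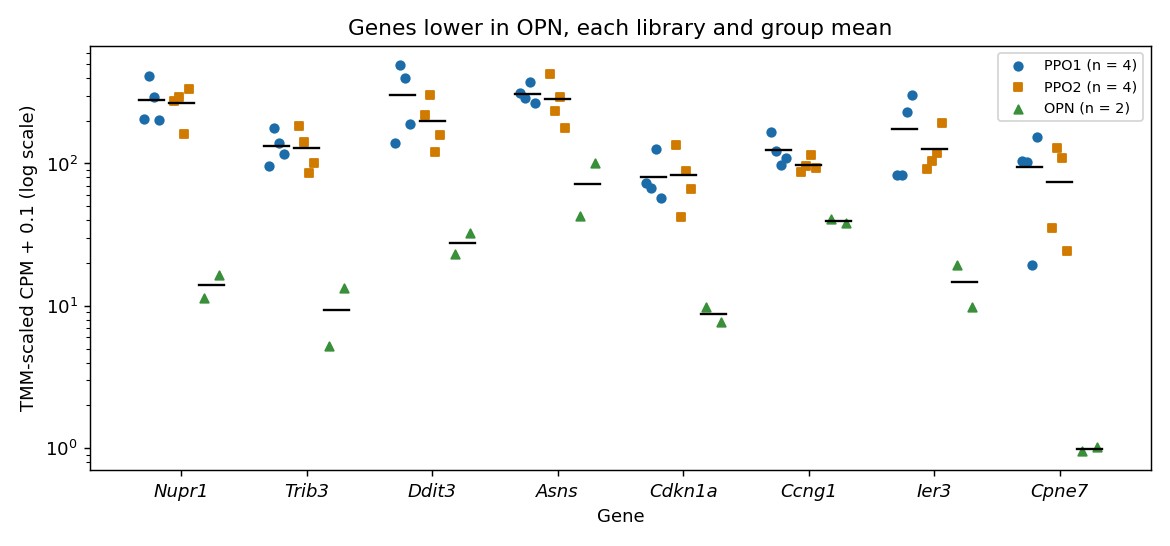
TMM-scaled CPM + 0.1 on a log axis for genes lower in OPN, with 1 point per library and a bar at each group mean. The OPN points of Nupr1 lie at 11.3 and 16.3 CPM, below the PPO libraries at 161 to 413 CPM.

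Of the 16 tested heat shock and unfolded protein response genes, 3 fell in OPN against PPO1, none rose and 13 did not pass. Those that fell were Trib3 (-3.85 ± 0.53), Ddit3 (-3.46 ± 0.63) and Asns (-2.10 ± 0.44), a pseudokinase, a transcription factor and asparagine synthetase, which are known targets of the transcription factor ATF4. Adjusted over the list alone 7 were lower, and the list was lower by camera (median -1.13, adjusted p = 0.000332; adjusted p = 0.414 with an estimated correlation). Of 21 p53 target genes, Cdkn1a (-3.23 ± 0.54) and Ccng1 (-1.65 ± 0.26) fell and 19 did not pass, although both groups carried floxed Trp53. Of its members 6 were lower when adjusted over the list alone, and the median was -0.73 (camera adjusted p = 0.0118; adjusted p = 0.414 with an estimated correlation). Among 23 RAS-MAPK output genes, which included feedback inhibitors, Ier3 (-3.58 ± 0.69) and Il1rap (-2.27 ± 0.46) fell and 21 did not pass. Adjusted over the list alone 4 were lower, with a median of -0.93 (camera adjusted p = 0.0242; adjusted p = 0.621 with an estimated correlation). Ier3 was also the 1 called member of 14 immediate-early genes, 3 of which were lower when adjusted over the list alone, with a median of -1.51 (camera adjusted p = 0.00797; adjusted p = 0.621 with an estimated correlation).

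The 12 tested replication-dependent histone genes were all higher in OPN than in PPO1, with a median of 2.36 (camera adjusted p = 0.000332; adjusted p = 0.551 with an estimated correlation). Hist1h4h rose from 0.632 ± 0.081 to 6.39 ± 1.72 CPM, 11 members did not pass, and 4 were higher when adjusted over the list alone; these near-identical genes may share reads. The 13 mitochondrially encoded genes were all lower, with a median of -0.67 (camera adjusted p = 0.000332; adjusted p = 0.621 with an estimated correlation). None passed singly and 4 were lower when adjusted over the list alone; COX1 and ND4, subunits of the respiratory chain, had values of -0.46 ± 0.28 and -0.71 ± 0.31. Mitochondrial genes took 1.63% and 2.25% of the counts in the OPN libraries and 2.66% to 4.23% in the PPO libraries, and a GC correction moved the list's median to -0.37.

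Of 20 astrocyte genes 18 were higher in OPN than in PPO1, none passed singly and 3 were higher when adjusted over the list alone, with a median of 1.56 (camera adjusted p = 0.00173; adjusted p = 0.595 with an estimated correlation). The lipid carrier Apoe was at 2630 ± 294 CPM in OPN and 918 ± 689 CPM in PPO1, and Sparcl1 at 1816 ± 59.6 and 1649 ± 523 CPM. Of 12 Hedgehog genes, Gli2 (2.45 ± 0.49), a transcription factor of the pathway, and Sufu (1.37 ± 0.23), its inhibitor, rose and 10 did not pass. Of its members 3 were higher when adjusted over the list alone, with a median of 1.19 (camera adjusted p = 0.0166; adjusted p = 0.414 with an estimated correlation). The oligodendrocyte progenitor list was higher with no called member, also when adjusted over the list alone, and a median of 0.81 (camera adjusted p = 0.0248; adjusted p = 0.621 with an estimated correlation). Its members Ptprz1 and Ncan had values of 1.01 ± 0.71 and 2.22 ± 0.71. The interferon response list had no called member either way and a median of 1.03 (camera adjusted p = 0.0452; adjusted p = 0.864 with an estimated correlation). Stat1, a transcription factor of that response, was at 146 ± 85.9 CPM in OPN and 58.0 ± 48.9 CPM in PPO1, and the RNA sensor Ddx58 at 87.1 ± 56.2 and 69.8 ± 58.4 CPM. Of 14 microglia and macrophage markers 13 were higher and 1 was lower in OPN, with none called either way and a median of 2.11 (camera adjusted p = 0.115). Among them, the macrophage gene Laptm5 was at 79.6 CPM in OPN replicate 2, 0.14 CPM in OPN replicate 3 and 25.3 CPM in PPO1 replicate 4. Of 25 extracellular matrix genes 23 were lower with none called either way and a median of -1.86 (camera adjusted p = 0.0442; adjusted p = 0.816 with an estimated correlation). Sparc and Tnc had values of 0.02 ± 0.78 and -1.74 ± 1.19. The pericyte and fibroblast markers, which share 5 genes with the matrix list, had 12 of 15 members lower with none called and a median of -2.60 (camera adjusted p = 0.697). Of these, Col3a1 was at 296 and 40.8 CPM in PPO1 replicates 4 and 3, 0.09 and 0.15 CPM in PPO1 replicates 1 and 2 and 4.14 and 0.53 CPM in OPN, and Notch3 had a log2 fold change of 1.91 ± 0.68.

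Other lists held 1 or 2 called genes. Sox4, a progenitor transcription factor of the transit-amplifying list, rose by 1.58 ± 0.33, the collagen receptor gene Ddr1 by 1.62 ± 0.30 and the FOXO target Sesn3 by 1.34 ± 0.27. The kinase gene Cdk6 fell by 1.65 with Cdkn1a among the cell-cycle regulators. Of 16 Notch pathway genes the ligand gene Jag1 fell by 1.92 and 15 did not pass, while 12 lay higher, with a median of 1.16, and 5 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0705; adjusted p = 0.414 with an estimated correlation). The 22 lists that camera did not call in OPN vs PPO1 had adjusted p-values of 0.0543 to 0.973, and the Wnt, Hox and FOXO target lists among them had a median below 0 and a test direction above 0. By fry, 4 of the 33 lists passed, the lowest adjusted p being 0.0496. These were the p53 target, heat shock and unfolded protein response, Hedgehog and transit-amplifying lists, and camera did not call the transit-amplifying list.

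In all, 462 of 19380 genes were called between OPN and PPO1 by edgeR's quasi-likelihood test, 276 higher and 186 lower, with a median absolute log2 fold change of 1.76. The share of calls that were higher was 59.7%, and 49.2% with library totals alone. It was 49.6% of 631 calls with the filter of 1 CPM in at least 4 libraries and 44.6% with DESeq2. Without a filter it was 66.4%, and in the limma fits 60.8% to 78.8%. Without PPO1 replicate 2, PPO1 replicate 4, OPN replicate 2 or OPN replicate 3, edgeR called 0 genes, with 3878, 4036, 2317 and 2492 at an unadjusted p under 0.05, and without PPO1 replicate 3 it called 235; with all libraries DESeq2 called 2701. A fit of only these groups and glmTreat called 0 (4691 and 1625 at an unadjusted p under 0.05), a fit without a filter 238, GC-corrected counts 177 and limma on TPM values 898 to 1180. The camera call ended for the progenitor list without PPO1 replicate 2 (adjusted p = 0.104) or OPN replicate 3 (0.121), for RAS-MAPK without OPN replicate 3 (0.104), for interferon without PPO1 replicates 1, 2 or 3 (0.190, 0.0516, 0.166) or OPN replicate 2 (0.720), and for extracellular matrix without PPO1 replicates 3 or 4 (0.167, 0.262) or OPN replicate 3 (0.214).

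OPN was then compared with PPO2, from which it differs in the Cre driver as well as in Nf1 against Pten. Genes that rose in OPN included Gpr17, Ntrk2 and Gja1. Gpr17, a receptor of committed oligodendrocyte progenitors, was at 607 ± 376 CPM (SD, n = 2) in OPN and 6.87 ± 6.92 CPM (SD, n = 4) in PPO2, 88.2-fold higher. Ntrk2, which encodes the neurotrophin receptor TrkB, was at 1911 ± 79.5 and 218 ± 79.8 CPM, 8.77-fold higher, and Gja1, an astrocyte gap junction gene, at 810 ± 264 and 66.8 ± 24.6 CPM, 12.1-fold higher. Nupr1 was 19.2-fold lower, at 13.8 ± 3.54 CPM in OPN and 265.7 ± 74.7 CPM in PPO2, and Cdkn1a was 9.60-fold lower, at 8.62 ± 1.47 and 82.7 ± 39.5 CPM.

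The 10 largest rises by the naming rule in OPN vs PPO2 were Mpped1, A2m, Gpr17, Ap3b2, Ntsr2, Baalc, Hr, Prkcq, Scg3 and Sox3, from 7.49 ± 1.67 for Mpped1 to 5.25 ± 0.69 for Sox3. The 10 largest falls were Cpne7, Lgi2, Tead4, Xdh, Clic5, Cth, Sphk1, Nupr1, Gch1 and Fbln1, from -6.38 ± 1.14 for Cpne7 to -4.17 ± 0.84 for Fbln1. Tead4, a transcription factor of the Hippo pathway, had a log2 fold change of -5.23 ± 1.22, Xdh, which encodes xanthine dehydrogenase, -5.02 ± 0.95, and Gch1, an enzyme of tetrahydrobiopterin synthesis, -4.26 ± 0.91. The edgeR adjusted p-values of these 20 genes lay between 0.0139 and 0.0479.

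Of 20 oligodendrocyte progenitor genes 18 were higher in OPN than in PPO2, and Gpr17 (6.46 ± 1.32) and Lims2 (4.14 ± 0.85) rose. Gpr17 lies within Lims2 (chromosome 18, 31942999 to 31949890 in 31922293 to 31958620), so reads may be shared and these may not be separate changes. Of its members 7 were higher when adjusted over the list alone, with a median of 2.15 (camera adjusted p = 5.02e-05; adjusted p = 0.324 with an estimated correlation). Of 20 astrocyte genes 18 were higher, and Gja1 (3.60 ± 0.81) and Sox9 (2.10 ± 0.47), a glial transcription factor, rose. Of its members 10 were higher when adjusted over the list alone, with a median of 2.03 (camera adjusted p = 1.26e-05; adjusted p = 0.324 with an estimated correlation). Among 23 receptor tyrosine kinases Ntrk2 (3.13 ± 0.44) and Ddr1 (2.21 ± 0.30) rose, 21 did not pass, and the same number, 2, was called when adjusted over the list alone. The median was 0.51 (camera adjusted p = 0.0417; adjusted p = 0.324 with an estimated correlation). All 12 replication-dependent histone genes were higher, Hist1h3b (3.78 ± 0.90) and Hist1h4h (3.19 ± 0.72) rose, and 4 were higher when adjusted over the list alone. Both lay under 10 CPM in every group, at 0.787 ± 0.078 and 6.39 ± 1.72 CPM in OPN. The list median was 2.06 (camera adjusted p = 1.26e-05; adjusted p = 0.324 with an estimated correlation). Of 14 microglia and macrophage genes 13 were higher, none passed singly and 2 were higher when adjusted over the list alone, with a median of 5.16 (camera adjusted p = 0.0486; adjusted p = 0.791 with an estimated correlation). Laptm5 was at 79.6 and 0.14 CPM in OPN replicates 2 and 3 and at 0.844 ± 0.524 CPM in PPO2. Cd68, the member with the highest mean level, had a log2 fold change of -1.03 ± 0.76, against the direction of the list.

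Of 16 heat shock and unfolded protein response genes 4 fell in OPN against PPO2. They were Trib3 (-3.80 ± 0.52), Ddit3 (-2.85 ± 0.61), Asns (-1.97 ± 0.44) and Chac1 (-1.90 ± 0.43), a glutathione-degrading enzyme. Of its members 6 were lower when adjusted over the list alone, with a median of -1.21 (camera adjusted p = 0.000165; adjusted p = 0.324 with an estimated correlation). Of 21 p53 targets 4 fell, namely Pmaip1 (-4.31 ± 0.75), Cdkn1a (-3.26 ± 0.54), Plk2 (-2.02 ± 0.46) and Ccng1 (-1.30 ± 0.25). Adjusted over the list alone 7 were lower and 1 higher, with a median of -0.99 (camera adjusted p = 0.000982; adjusted p = 0.324 with an estimated correlation). The RAS-MAPK genes Ier3 (-3.12 ± 0.68) and Spry4 (-2.40 ± 0.52), a feedback inhibitor of the pathway, fell and 21 members did not pass. Of its members 4 were lower when adjusted over the list alone, with a median of -1.07 (camera adjusted p = 0.00888; adjusted p = 0.562 with an estimated correlation). Of 20 hypoxia and glycolysis genes Vegfa (-2.06 ± 0.48) and Bnip3 (-1.68 ± 0.33) fell, and 3 were lower when adjusted over the list alone, with a median of -0.96 (camera adjusted p = 0.0123; adjusted p = 0.440 with an estimated correlation).

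The 13 mitochondrially encoded genes were all lower in OPN than in PPO2 with none called either way and a median of -0.67 (camera adjusted p = 0.000430; adjusted p = 0.652 with an estimated correlation). COX1 and ND4 had values of -0.45 ± 0.28 and -0.69 ± 0.31, and a GC correction moved the list's median to -0.39. Of 22 proliferation genes 20 were lower with none called either way and a median of -0.95 (camera adjusted p = 0.0125; adjusted p = 0.791 with an estimated correlation). Top2a, a mitotic topoisomerase, was at 50.4 ± 20.9 CPM in OPN and 148.8 ± 95.5 CPM in PPO2, and Pcna, a replication factor, at 53.8 ± 1.90 and 94.6 ± 22.04 CPM. Of 25 extracellular matrix genes 19 were lower, none passed singly, and 2 were lower and 1 higher when adjusted over the list alone, with a median of -2.22 (camera adjusted p = 0.0195; adjusted p = 0.791 with an estimated correlation). Sparc and Tnc had values of 0.31 ± 0.77 and -2.85 ± 1.27. With none called, 12 of 15 pericyte and fibroblast markers were lower (median -1.79, camera adjusted p = 0.432), with Col3a1 at -3.64 ± 2.79 and Notch3 at 1.73 ± 0.68, and so were 10 of 12 endothelial markers (median -1.11, camera adjusted p = 0.432), with Ly6c1 at -3.48 ± 2.51 and Flt1 at 2.04 ± 1.16. Called genes of other lists included Cnp (2.38 ± 0.48), a myelin enzyme gene, Sox4 (1.61 ± 0.33), Sesn3 (1.20 ± 0.27) and Sufu (1.0 ± 0.23), which rose, and Jag1 (-2.22 ± 0.41) and, with Cdkn1a among the cell-cycle regulators, Cdk6 (-1.89 ± 0.37), which fell. Against the direction of Jag1, 11 of the 16 Notch genes lay higher, with a median of 1.22, and 5 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0717; adjusted p = 0.324 with an estimated correlation; fry adjusted p = 0.0426). Adjusted over the list alone, 3 Hedgehog genes were higher and 1 lower, and 1 cell-cycle regulator was higher and 2 were lower. The 21 lists that camera did not call had adjusted p-values of 0.0717 to 0.986, and by fry 8 of 33 lists passed, the lowest adjusted p being 0.0237. Those that passed fry were the progenitor, astrocyte, p53 target, receptor tyrosine kinase, heat shock, histone, transit-amplifying and Notch lists. Camera did not call the transit-amplifying or Notch list. Among the uncalled lists, Wnt had a median below 0 and a test direction above 0, and cholesterol synthesis the opposite.

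**Figure D4:**
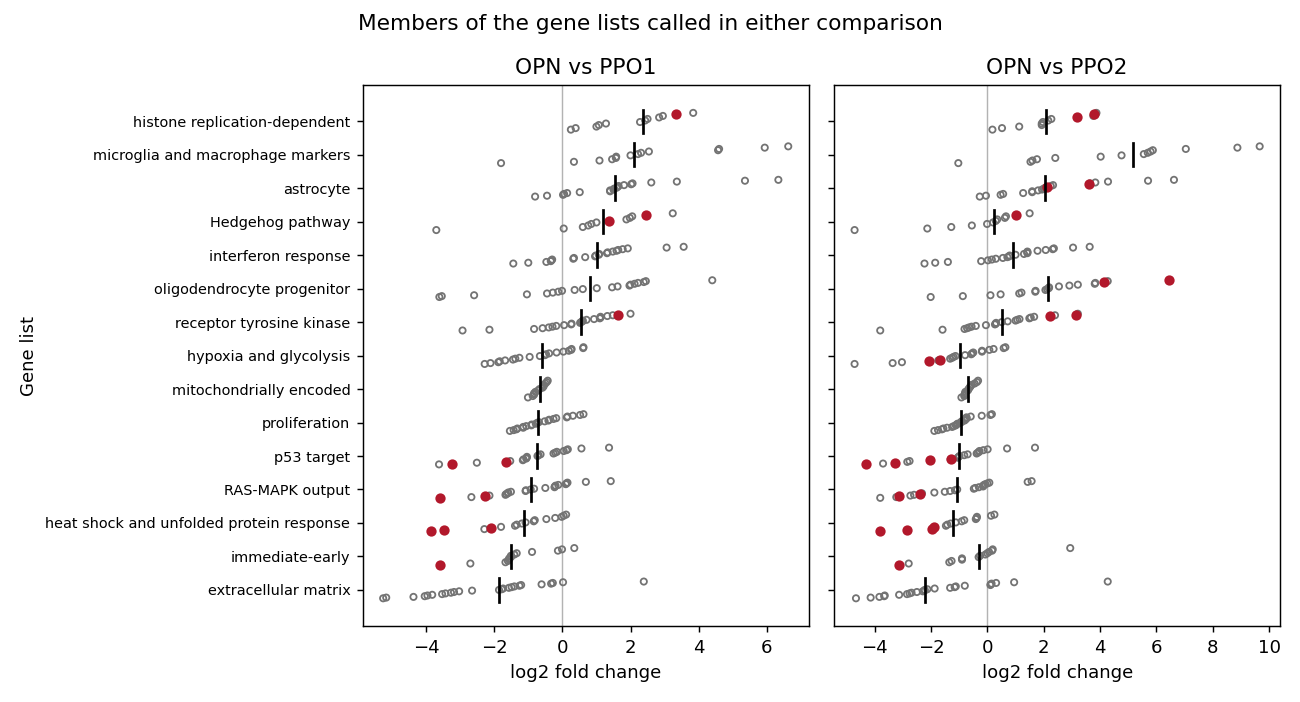
Log2 fold changes in OPN vs PPO1 and OPN vs PPO2 on the horizontal axis for the members of the gene lists called in either comparison, with 1 point per gene, filled red where edgeR's adjusted p was under 0.05, and a black line at each list's median. All 12 histone genes lie above 0 and all 13 mitochondrially encoded genes below 0 in both comparisons.

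In all, 770 genes were called between OPN and PPO2 by edgeR's quasi-likelihood test, 450 higher and 320 lower, with a median absolute log2 fold change of 1.87. The share of calls that were higher was 58.4%, and 42.7% with library totals alone. It was 51.7% of 862 calls with the filter of 1 CPM in at least 4 libraries and 45.7% with DESeq2. Without a filter it was 64.0%, in a fit of only these groups 69.1%, and in the limma fits 56.7% to 74.6%. Without OPN replicate 2 or 3 edgeR called 0 genes, with 2682 and 2734 at an unadjusted p under 0.05, and without PPO2 replicates 1, 2, 3 or 4 it called 8, 158, 441 and 391; with all libraries DESeq2 called 3184. A fit of only these groups called 366, glmTreat 1, a fit without a filter 455, GC-corrected counts 495 and limma on TPM values 1226 to 1432. The camera call ended for proliferation without PPO2 replicate 4 (adjusted p = 0.0993) or OPN replicate 3 (0.120), for RAS-MAPK without OPN replicate 3 (0.0524), for receptor tyrosine kinases without PPO2 replicates 1 or 2 (0.151, 0.0749) or OPN replicate 2 (0.0647), for extracellular matrix without PPO2 replicates 3 or 4 (0.0574, 0.0738) or OPN replicate 3 (0.111), for mitochondrial genes without OPN replicate 2 (0.0852), and for microglia without any PPO2 library (0.0560 to 0.107) or OPN replicate 2, where the direction turned (0.450).

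Both OPN comparisons called 363 genes in the same direction, 202 higher and 161 lower, and 0 in opposite directions. Among these, Hr, Sox3, Baalc, A2m and Sufu rose in OPN, and Nupr1, Cdkn1a, Trib3, Ddit3, Asns, Cth and Jag1 fell. Independent lists of these sizes would share 6.4 higher and 3.1 lower genes, but these comparisons share the OPN libraries and are not independent. Unchanged groups that shared the OPN libraries gave 0 shared calls in each of 20 simulations. With no gene changed, hardly any call is possible in either comparison, so this 0 cannot show what the shared libraries add. Fold changes of both comparisons had a correlation across genes of 0.83, against 0.70 in the simulations, and a covariance of 1.94 against 0.59; genes are not independent replicates. The OPN libraries are too few to be split, so part of the overlap may come from the shared libraries, and how much cannot be told. The overlap was 0 without PPO1 replicate 2, PPO1 replicate 4, OPN replicate 2 or OPN replicate 3, and 213, 8, 112 and 210 without PPO1 replicate 3 and PPO2 replicates 1, 2 and 4. Over the whole set of 19380 genes, edgeR called more genes in each OPN comparison than between PPO2 and PPO1, and no test of the difference between these counts was made.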

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

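The genes of the closing section, such as Acan, Col9a1, Csf1r and Lyz2, were chosen after their values were seen, some because libraries stood apart, so their passing values are not chance draws. Dixon's test compared the highest or lowest library of each group of 4 with the nearest other library, for the library measures and the genes named in the report and the closing section. Of 234 such groups 28 passed the 0.05 critical value for 4 libraries, and chance alone gives about 1 in 20, or 11.7. The passing values include 10 of PPO1 replicate 4, 5 of PPO1 replicate 1 and 4 of PPO2 replicate 3, and their explanations were not tested.

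In PPO1 replicate 4, a far value against the other PPO1 libraries was seen for Xdh at 43.1 CPM (nearest 12.7), Laptm5 at 25.3 CPM (nearest 1.09), Ddx3y at 66.7 CPM (nearest 0.61), Tnc at 1599.7 CPM (nearest 328), Stat1 at 130.81 CPM (nearest 42.3), Col3a1 at 295.68 CPM (nearest 40.8), Ly6c1 at 61.07 CPM (nearest 7.6), Csf1r at 2.82 CPM (nearest 0.37) and Lyz2 at 82.75 CPM (nearest 0.76), all higher, and for Tspan18 at 19.0 CPM (nearest 37.2), lower. In PPO1 replicate 1, Aldh1a1 was at 8.13 CPM (nearest 2.97), Sufu at 34.2 CPM (nearest 29.8), Ap3b2 at 15.4 CPM (nearest 3.01) and Prkcq at 28.7 CPM (nearest 4.07), all higher, and 22534 genes had a count (nearest 23466). In PPO1 replicate 2, Mpped1 was higher at 1.77 CPM (nearest 0.09) and Lims2 lower at 2.28 CPM (nearest 20.04). In PPO1 replicate 3, Acan was at 442.89 CPM (nearest 2.04) and Col9a1 at 579.91 CPM (nearest 5.56), both higher.

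In PPO2 replicate 3, Wnt5b was at 8.59 CPM (nearest 2.21), Pmaip1 at 29.0 CPM (nearest 10.8), Csf1r at 1.36 CPM (nearest 0.12) and Lyz2 at 18.29 CPM (nearest 0.21), all higher than in the other PPO2 libraries. Xdh and Aqp4 were higher in PPO2 replicate 4, at 43.7 CPM (nearest 18.3) and 76.26 CPM (nearest 4.81). In PPO2 replicate 1, Ddx58 was lower, at 35.4 CPM (nearest 57.9), and Col9a1 and Cspg4 were higher, at 10.56 CPM (nearest 1.0) and 426.88 CPM (nearest 92.9).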

How the results depend on the processing

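The GC correction and the thinning in this part were chosen after the data were seen. Of the named genes, 33 of 79 were called in OPN vs PPO1 and 45 of 82 in OPN vs PPO2. None of these called genes changed direction under any alternative run. The largest rises and falls were chosen without overlap between libraries, so their direction could hardly change. None was called under every alternative, which follows from runs such as glmTreat that called few or no genes at all. Of the named genes that were not called, 15 and 12 changed sign under at least 1 alternative, and so did 34 of 67 in PPO2 vs PPO1. Scaling by RLE gave 477 and 777 genes, 457 and 763 of them shared with TMM, and 0 for PPO2 vs PPO1 (1044 at an unadjusted p under 0.05). Library totals alone gave 463 and 899 genes and moved the median log2 fold change of all genes from -0.073 to -0.139 in OPN vs PPO1 and from -0.078 to -0.216 in OPN vs PPO2, and directions of small changes are relative to that shift. Thinned libraries gave 472 and 723 genes, so unequal totals were not needed for counts of this size. Whether more depth would bring more calls was not tested.

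Counts moved by over 1.5 times under other settings. For PPO2 vs PPO1, no filter gave 1 gene and DESeq2 66. For OPN vs PPO1, no filter gave 238 genes, all shared, with 30758 genes in the adjustment in place of 19380. DESeq2 gave 2701, sharing 461. A fit of only the compared groups gave 0 for OPN vs PPO1 (4691 at an unadjusted p under 0.05) and 366 for OPN vs PPO2, with fewer libraries to estimate the spread, and glmTreat gave 0 (1625) and 1. The limma fits gave 1180 for OPN vs PPO1 on log2(TPM + 1), 898 on log2(TPM + 0.1) and 1151 without a filter. For OPN vs PPO2, no filter gave 455 genes, DESeq2 3184 (762 shared), and the limma fits 1432, 1226 and 1298. The GC correction gave 177 and 495 genes, 172 and 468 of them shared. The overlap of the OPN comparisons was 1938 with DESeq2. The causes of these shifts were not tested.

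With each library left out in turn, edgeR called 0 to 0 genes for PPO2 vs PPO1, 0 to 342 for OPN vs PPO1 and 0 to 441 for OPN vs PPO2, and the overlap was 0 to 347. Where an OPN library was left out, the lone sample was assumed to vary like the other groups. The microglia list in OPN vs PPO2 turned from a camera score of 1.75 to -0.42 (signed -log10 p) without OPN replicate 2 (adjusted p = 0.450), and stood at 12.64 without OPN replicate 3.

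Replicate numbers 1 to 4 gave correlations of the deviations of PPO1 and PPO2 libraries of 0.08, 0.45, 0.03 and 0.32, and pairs with different numbers -0.46 to 0.37. Not every library correlated best with its own number, as PPO1 replicate 1 had 0.31 with PPO2 replicate 2, and the libraries were not treated as paired. The highest values, 0.45, 0.37, 0.32 and 0.31, all lay within replicates 1 and 2 or within replicates 3 and 4. Other pairs within these sets had -0.01 to 0.08, and pairs between the sets -0.46 to 0.15. No fit had a term for these sets or for sex, so in the main fit deviations they share count as spread within the groups. Correlations with the OPN libraries mirror each other by centring and say nothing on pairing. With the replicate block edgeR called 0 genes for PPO2 vs PPO1 (766 at an unadjusted p under 0.05) and 0 for OPN vs PPO1 (4297). It called 50 for OPN vs PPO2, with an overlap of 0. The block ended the camera call of the extracellular matrix list in both comparisons (adjusted p = 0.0989 and 0.0525) and of the proliferation list in OPN vs PPO2 (adjusted p = 0.203), and library totals alone ended that of the extracellular matrix list (0.0651 and 0.0540).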

Other observations

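The genes of this paragraph and the next, the S-phase, p53-specific and mitochondrial GC tests, the count of splits at an unadjusted p, the OPN counts in the fits with 2 PPO2 libraries, the chromosomes of the split's genes, the list tests of the ATF4 targets and their test without Cth, and the demand that the median of the non-polyadenylated RNAs exceed its spread were chosen after results were seen. Genes that rose in OPN included Srebf1, Gpam, Fasn and Mgat5. Srebf1, a transcription factor of lipid synthesis, was at 678 ± 38.7 CPM (SD, n = 2) in OPN, 159 ± 35.4 CPM (SD, n = 4) in PPO1 and 148 ± 26.6 CPM (SD, n = 4) in PPO2. Its log2 fold changes were 2.10 ± 0.24 and 2.19 ± 0.24 (edgeR adjusted p = 0.0184 and 0.0139). Gpam, an acyltransferase of glycerolipid synthesis, rose by 3.27 and 4.01, and the fatty acid synthase gene Fasn by 1.59 and 1.49. The desaturase genes Scd1 and Scd2 were not called (edgeR adjusted p = 0.105 and 0.0605 for Scd1, 0.179 and 0.0694 for Scd2). Mgat5, an N-glycan branching enzyme gene, rose by 2.69 and 2.75. The astrocyte genes Gfap and Aqp4 were at 4312 ± 2026 and 1073 ± 317 CPM in OPN and at 53.3 ± 49.9 and 26.2 ± 29.4 CPM in PPO1, without a call (edgeR adjusted p = 0.0652 and 0.117).

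Some libraries held transcripts that others of their group lacked. In PPO1 replicate 3 the cartilage matrix genes Col9a1 and Acan were at 579.9 and 443 CPM, while the other libraries had at most 10.6 and 5.92 CPM. The progenitor genes Cspg4 and Sox10 were at 1290.3 and 454 CPM in that library, against at most 427 and 228 CPM elsewhere, and Egfr and Foxg1 at 4.07 and 0.76 CPM. The posterior patterning gene Hoxa9 was at 142 CPM in PPO2 replicate 3, 47.5 CPM in PPO2 replicate 4, 11.3 CPM in PPO2 replicate 1 and at most 1.56 CPM in the other libraries. The macrophage genes Lyz2 and Csf1r were at 472 and 42.3 CPM in OPN replicate 2, 82.8 and 2.82 CPM in PPO1 replicate 4, 18.3 and 1.36 CPM in PPO2 replicate 3, and 0.112 and 0.281 CPM in OPN replicate 3.

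Replication-dependent histone genes had a median log2 fold change of 2.36 and 2.06, and mitochondrially encoded genes of -0.67 and -0.67, in OPN vs PPO1 and OPN vs PPO2. For a larger share of cells in S phase, 8 S-phase genes had medians of 0.14 and -0.67 (SD 0.43 and 0.44). These lay below the 1.18 and 1.03 set as a cut-off from the histone medians, which a larger share need not reach. In OPN vs PPO2 the negative median went against the direction of a larger share, and in OPN vs PPO1 the median lay within its SD. These SDs are over genes, not libraries, and do not measure the spread between samples. The proliferation list was also lower in OPN vs PPO2, but not with an estimated correlation (camera adjusted p = 0.791). The S-phase genes therefore cannot decide in either comparison. GC content is argued against for the histones by medians of 2.18 and 1.95 after GC correction. For the mitochondrial genes the correction moved the medians to -0.37 and -0.39, so GC content cannot be told apart from another source of part of that shift. RNA selection that kept more non-polyadenylated RNA in OPN stays open. The 76 other such RNAs had medians of -0.46 and -0.69, against its direction, but within their spread (SD 0.99 and 0.96). In OPN vs PPO1, Rmrp and Rpph1 were higher (3.82 and 3.51) and Snora65 was lower (-2.49). Rmrp and Rpph1 were low in OPN, at 0.68 and 2.16 CPM. Many non-polyadenylated RNAs may come from host introns. By the rule set before these values were seen, negative medians would have argued against such RNA selection. The later demand that they exceed their spread changed this reading. A batch of libraries or cultures would coincide with the OPN group, the labels give none, and the deletion of Nf1 in place of Pten also stays open, as untested.

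Genes were called in both OPN comparisons and none between PPO2 and PPO1 by edgeR (1050 at an unadjusted p under 0.05, 66 by DESeq2). Sequencing depth is argued against by the 472 genes called in OPN vs PPO1 after thinning. For the small OPN group, each of the 6 pairs of PPO2 libraries gave 0 calls against PPO1 by edgeR (472 to 1953 at an unadjusted p under 0.05). In the same fits of 8 libraries OPN vs PPO1 gave 15 to 479 (4316 to 4859). A group of 2 PPO2 libraries thus brought no calls by its size alone in these fits. All PPO2 libraries together also gave 0, and they correlated at 0.917 to 0.951, against 0.971 within OPN. Whether 2 libraries as alike as those of OPN would bring calls by chance was not tested, so the small group stays open. In a fit of only OPN and PPO1, OPN vs PPO1 gave 0 as well (4691), so these counts hold only for fits with all groups. The real split of PPO2 and PPO1 gave 0 genes, which each of the 35 splits of those 8 libraries reaches by construction, so this count says nothing on chance; the highest other split gave 57. Chance cannot be excluded for the genes at an unadjusted p under 0.05, of which the real split gave 1050: 17 of the 35 splits gave as many, the highest other 3705. The split with 57 genes set PPO1 replicates 1 and 2 and PPO2 replicates 1 and 2, the libraries with 364 to 489 CPM of Xist, against the rest, which may point to a structure of the samples across the driver groups; of its genes 3 lie on the X chromosome and 0 on the Y. It is the highest of 35 splits, and whether 57 is more than chance gives for the highest was not tested. A batch or culture difference that coincides with OPN and the Nf1 genotype stay open, since the labels cannot separate them.

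Of 21 p53 targets 2 and 4 fell in OPN against PPO1 and PPO2, and of 16 heat shock and unfolded protein response genes 3 and 4, among them Cdkn1a, Trib3 and Ddit3. Both lists lost their camera call with an estimated correlation (adjusted p = 0.414 for each against PPO1 and 0.324 for each against PPO2). By fry both passed (adjusted p = 0.0496 for each against PPO1 and 0.0237 for each against PPO2). GC content is argued against as the whole cause for Cdkn1a, which had a log2 fold change of -3.38 ± 0.54 in OPN vs PPO1 after GC correction and -3.23 ± 0.54 before it. A difference in p53 activity cannot be told apart from other causes, as 10 p53 targets not known as ATF4 targets had medians of -0.65 and -0.68 with SDs of 1.39 and 1.59, from Perp at -3.62 to Fas at 1.37 in OPN vs PPO1. A candidate explanation is a lower ATF4 programme, which answers amino acid shortage: 22 ATF4 targets outside the gene lists had medians of -1.17 and -1.11, at percentile 0.01 of random lists in both comparisons, the smallest that 10000 lists can give, with Mthfd2 (-2.93 and -3.26) and Vldlr (-2.23 and -2.31) among 5 and 6 that fell. Cth, 1 of these, was already known as a large fall; without it the medians were -1.16 and -1.11, also at percentile 0.01, with 4 and 5 that fell. Random lists leave out the correlation between genes: with an estimated correlation camera gave p = 0.0962 and 0.0907 for the ATF4 targets (fry p = 0.00599 and 0.00395) and p = 0.101 and 0.0973 without Cth, and both comparisons share the OPN libraries, so they are not independent. Whether this may reflect genotype, culture density or medium at harvest stays open, since the labels give nothing that would tell these apart within OPN.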
